A study of Mus musculus with 2 samples.

How the data were processed

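The data are 2 single-cell RNA-seq libraries of sorted mouse Pax2-lineage renal progenitors, 1 from cells given vehicle and 1 from cells given 0.2 µM panobinostat. Per the labels' protocols, 3′ gene expression libraries were made on the 10x Chromium instrument and sequenced on an Illumina NextSeq500. Per the submitters' processing notes, Cell Ranger 3.0.1 and the mouse build mm10 were used, with no further role given. The annotation used for counting is not given in the sources used here.

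The deposited matrix holds raw UMI counts, that is whole numbers of distinct molecules per gene and cell, for 19394 genes and 5135 cells, with no normalization by the authors. Cells are assigned to libraries by a mark at the end of each barcode, read as control for vehicle and as the drug's name for panobinostat. Genes carry symbols without identifiers, with 0 duplicated symbols, and 98.7% of the symbols occur in GENCODE M21, from which gene coordinates on GRCm38, the assembly of mm10, were taken by unique symbol. The deposited cells had at least 1798 genes and at most 9.98% mitochondrial counts, and each gene was seen in at least 3 cells, so cells and genes had been filtered before deposit by rules not given in the sources used here. The planned filter of 500 genes and 20% mitochondrial counts therefore removed 0 cells, and no 16-base barcode was present in both libraries.

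Counts were summed over all cells of a library and scaled to a library total of 1000000 UMIs (CPM). The log2 ratio of CPM was taken as panobinostat over vehicle, with an exact conditional binomial (Clopper-Pearson) 95% interval, and single CPM values have exact Poisson intervals. A gene was called higher or lower when its ratio was at least 2-fold, its interval excluded equality and it reached 10 CPM in at least 1 library. A gene below 10 CPM in 1 library passes this floor only through the other, which favours a call in that direction. The calls follow a rule of size for 2 libraries, not a test of treatments: cells are not replicates and no p-value was computed. The intervals and floors leave out all variation between cells, cultures, animals and libraries. A gene with 0 UMIs in a library was set at 3 counts to give a fold, which leaves out the counting error of the other library. The 3 counts equal 0.0331 CPM in the vehicle library and 0.0288 CPM in the panobinostat library.

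For each of 36 gene lists, 34 fixed by symbol and 2 by name pattern, the median log2 ratio of members past the floor was given with its percentile among 10000 random lists matched on mean CPM in 20 bins. Some list members were not analysed here because the matrix used holds no row under their symbol. The named genes are, among genes with at least 50 CPM in 1 library and 10 UMIs in each, the 14 with the largest and the 14 with the smallest ratio, leaving out mitochondrial, ribosomal protein and unnamed genes. Also named are up to 4 members per list with the largest absolute log2 ratio, 10 genes always named, and up to 5 of the 10 defining genes of a cluster. The 36 lists, the rule and all but 2 of the alternatives were fixed before the data were examined, and lists and tests added later are named as such where they are used. Values of some genes under these rules are not reported here. The reporter transcript and some genes below the floor were named after their values were seen.

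For shares of cells and for phases, each cell was thinned without replacement to 18663 UMIs, the 10th percentile of cell totals, and shares have exact binomial (Clopper-Pearson) intervals. Phases were scored with scanpy 1.11.5 from the S and G2/M lists. For clusters, counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes gave 30 principal components, and a graph of 15 neighbours was split with leidenalg 0.10.2 at resolution 0.5. Scrublet, run per library, called 5 of 5135 cells doublets (0.0974%). Whether the caller missed doublets was not tested, so doublets may remain among the cells. The defining genes of a cluster had the largest fold of mean CPM over all other cells, with a pseudocount of 10 CPM, among genes seen in at least 25% of its cells.

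The alternatives were TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, centring on the median gene, other floors and folds, other choices of cells, a mean over cells, thinning before summing, and other cluster settings. The mean over cells has no counting interval and was judged by size alone. The comparison was tested on simulated counts drawn from the libraries' own means: of 50 genes each, it called 50 set at 3-fold, 48 set at 1/3, 50 set at 8-fold and 0 set at 1.5-fold, with 0 calls among 8089 unchanged genes past the floor. These counts hold counting noise only, so this checks the code and says nothing about variation between libraries. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3.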

Results

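Renal progenitors marked by Pax2 were profiled by droplet single-cell RNA sequencing after culture with panobinostat, a small-molecule inhibitor of histone deacetylases, or with DMSO vehicle. The cells grew out of glomeruli of 9-week-old C57Bl/6 mice in which the Pax2 promoter drives an inducible Cre, so that cells descended from Pax2-expressing cells turn from tdTomato to GFP. After 5 days of outgrowth the GFP-positive cells were sorted, starved for 16 h and exposed to 0.2 µM panobinostat or vehicle for 48 h. The labels give 2 mice and 1 library per treatment, so no spread between samples could be estimated and no test between treatments was run. Treatment cannot be told apart from any other difference between the 2 libraries, and every interval below covers counting error only.

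The vehicle library held 2854 cells and 90754967 UMIs, with a median of 27924 UMIs and 5492 genes per cell. The panobinostat library held 2281 cells and 104188927 UMIs, with a median of 42394 UMIs and 6589 genes per cell. Transcript of the GFP reporter, named after its values were seen, stood at 7601 CPM (UMIs scaled to a library total of 1000000) with vehicle and 7680 CPM with panobinostat, and 99.2% and 98.7% of cells held at least 1 of its UMIs. Of 19394 genes, 8872 reached 10 CPM in at least 1 library. Among these, 874 were at least 2-fold higher and 973 at least 2-fold lower with panobinostat, so that 47.3% of the genes called were higher. With DESeq2 size factors the split was 731 higher and 1249 lower, or 36.9% higher. The median log2 ratio over all genes past the floor was -0.07 with CPM and -0.19 with TMM factors, and list medians are to be read against that value.

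The purpose of the study, as its title states it, was the way panobinostat acts on these progenitors, and a question behind it is whether they turn towards podocytes, the filtering epithelial cells of the glomerulus. The podocyte genes Nphs1, Wt1, Podxl and Synpo stood at 11.8 CPM or lower in both libraries. Nphs1, which encodes the slit diaphragm protein nephrin, stood at 0.275 CPM with vehicle (25 UMIs) and 0.346 CPM with panobinostat (36 UMIs), a log2 ratio of 0.33 whose interval of -0.45 to 1.12 includes equality. Wt1, a transcription factor of podocytes and their precursors, had 0 UMIs with vehicle and 55 with panobinostat, at a level of 0.528 CPM. Against a floor of 3 counts it was 16.0-fold higher, and the 95% lower bound of its log2 ratio was 3.65. Podxl, which encodes podocalyxin, stood at 3.86 and 7.62 CPM. Synpo, which encodes the actin-binding protein synaptopodin, was 2.01-fold higher, at 5.86 and 11.8 CPM (log2 ratio 1.01, 95% interval 0.86 to 1.15).

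Of 31 podocyte genes fixed in advance, 13 passed the floor. Synpo was the 1 member at least 2-fold higher, and this call ended with TMM factors (log2 ratio 0.89), with DESeq2 factors (0.88) and over cells called G1 (0.61). None was at least 2-fold lower, and the list's median log2 ratio was 0.45, above 98.2% of 10000 random lists of matched expression. The sign-test interval of this median over the members, -0.07 to 0.76, includes 0. Among all genes past the floor 9.85% were higher and 10.97% lower. The cyclin-dependent kinase inhibitor Cdkn1c (28.8 and 55.9 CPM, log2 ratio 0.96), the basement membrane chains Col4a3 (0.76) and Lama5 (0.74) stayed under 2-fold. With the floor at 1 CPM, 6 of 23 members were at least 2-fold higher and 1 was lower, with a median of 0.70. Of all 13119 genes past that lower floor, 2344 were higher and 1448 lower. Over cells called G1 the list median was 0.23. Nphs1, Wt1 and Podxl stayed below the floor of 10 CPM in both libraries.

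Most genes of parietal epithelial cells and renal progenitors stayed under 2-fold. Pax2, the transcription factor that marks this lineage, stood at 40.4 CPM with vehicle and 24.9 CPM with panobinostat (log2 ratio -0.70, interval -0.77 to -0.63). Its relative Pax8 stood at 120.2 and 119.9 CPM. Of 19 members past the floor, 1 was at least 2-fold higher and 3 were lower, with a median log2 ratio of -0.43, which lay above 2.4% of matched random lists, at the edge of their 95% range (-0.43 to 0.30). The adhesion molecule Ncam1 was 4.46-fold higher (60.4 to 269.1 CPM). The keratin Krt8 was 2.68-fold lower (4587 to 1710 CPM), the adhesion molecule Vcam1 2.92-fold lower and the retinoic acid enzyme Aldh1a2 2.94-fold lower. Pax2 lies on chromosome 19 from 44756045 to 44837871 and Wt1 on chromosome 2 from 105126529 to 105173616 in GRCm38.

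**Figure D1:**
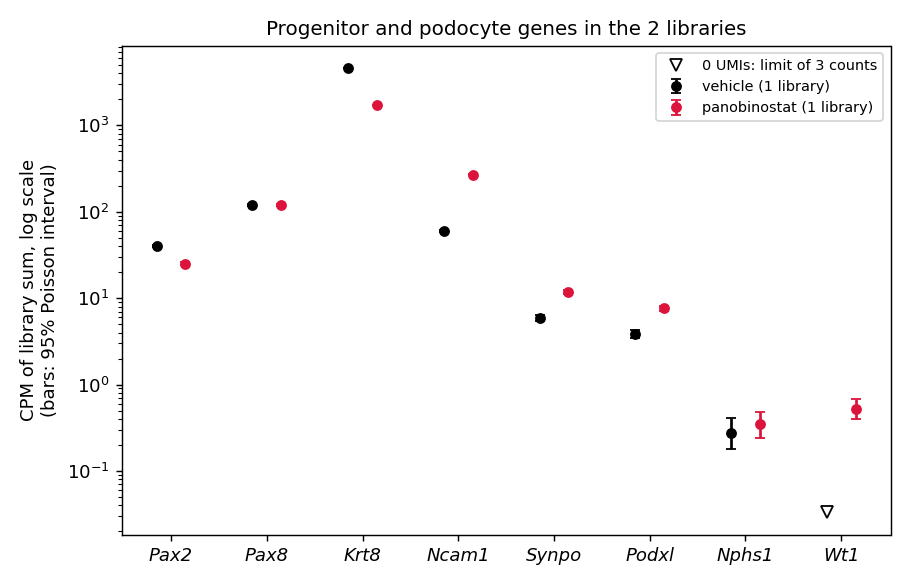
CPM of 8 progenitor and podocyte genes in the vehicle library (black) and the panobinostat library (red) on a log axis, with 95% Poisson intervals for counting error. Pax8 sits at 120.2 and 119.9 CPM, while Nphs1 and Wt1 lie below 1 CPM; the open triangle marks the limit of 3 counts where the vehicle library had 0 UMIs.

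Shares of cells with at least 1 UMI were compared after every cell was thinned to 18663 UMIs, which left out 453 vehicle and 60 panobinostat cells. The share with a UMI of Synpo was 9.16% with vehicle (exact binomial interval 8.04 to 10.4) and 19.05% with panobinostat (17.4 to 20.7), against 14.7% and 37.4% in unthinned cells. For Podxl it was 6.29% (5.35 to 7.34) and 11.6% (10.3 to 12.98), against 9.81% and 25.2% unthinned. Wt1 was seen in 0 of 2401 vehicle cells, which allows a share of up to 0.154%, and in 28 of 2221 panobinostat cells (1.26%), against 0% and 2.32% unthinned. The shares for Nphs1 were 0.541% and 0.765% with overlapping intervals, against 0.876% and 1.53% unthinned. Pax2 was seen in 48.7% of vehicle cells (46.7 to 50.8) and 35.3% of panobinostat cells (33.3 to 37.3), against 61.0% and 58.7% unthinned. For Pax8, whose CPM did not differ between libraries, no order is read from shares of 81.1% and 75.9%, which turned to 86.0% and 89.0% unthinned. The sorted cells hold no type known to lack these genes, so the part of these UMIs that came from free RNA is open.

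Cell-cycle genes made up most of the genes lowest with panobinostat. Of the 14 named for the smallest ratio, 13 act in DNA replication or mitosis. The cyclin Ccna2 was 399.4-fold lower (69.0 to 0.173 CPM, log2 ratio -8.64, interval -9.40 to -7.98), the PCNA-binding factor Pclaf had a log2 ratio of -8.13 and the cyclin Ccnb2 one of -7.87. Hmmr, Pbk, Plk1, Cdca3, Ccnb1 and Cdc20, which serve spindle assembly or the passage through mitosis, lay between -7.04 and -5.23. The proliferation marker Mki67 went from 132.5 to 1.68 CPM (-6.30, interval -6.53 to -6.09) and the topoisomerase Top2a from 256.7 to 6.15 CPM (-5.38). The replicative helicase subunit Mcm5 (-5.01) and survivin, Birc5 (152.3 to 4.76 CPM), completed this group. Ccna2 lies on chromosome 3 from 36564865 to 36572150 in GRCm38.

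Of 42 S-phase genes past the floor, 36 were at least 2-fold lower and 0 higher, with a median log2 ratio of -2.35, below all 10000 random lists. Of 53 G2/M genes, 48 were lower and 0 higher, with a median of -3.78, again below all random lists. Cdc6 (-6.30), Clspn (-5.78) and Cdc45 (-5.03), which act in DNA replication or its checkpoint, were the S-phase genes with the largest shifts beside Mcm5. Kif2c (-6.51) and Ttk (-6.43), which act at the kinetochore, stood out in the G2/M list beside Ccnb2 and Hmmr. In thinned cells 65.4% of vehicle cells (63.4 to 67.3) and 0.360% of panobinostat cells (0.156 to 0.708) scored as S or G2/M, against 64.3% and 0.219% unthinned. Phase scores are relative to the cells scored together, so these calls alone are not read as cycling. Over cells called G1 alone, which are picked by their low scores on these lists, the medians were 0.17 for S-phase and -0.38 for G2/M genes. These medians cover only members that still reached 10 CPM in those cells. Below that floor Hmmr (-2.85) and Cdc6 (-2.34) stayed past 2-fold and Clspn (-0.77) did not.

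Among 23 inhibitors of cyclin-dependent kinases and p53 targets, 5 were at least 2-fold higher and 1 was lower (median log2 ratio 0.29, above 98.3% of random lists). Cdkn2a, the locus of p16 and p19ARF, was 4.77-fold higher (81.8 to 389.7 CPM). The antiproliferative gene Btg2 (log2 ratio 1.84) and Trp53inp1 (1.34) were higher, while Trp53 itself was lower (243.5 to 92.1 CPM, -1.40). The call of Trp53inp1 ended over cells called G1 (0.72). Cdkn1a, which encodes p21 and is often raised by such inhibitors, stood at 512.6 and 626.9 CPM, a ratio under 2-fold (0.29). The cyclin Ccnd1, in the Wnt list, was 3.17-fold lower (1827 to 575.9 CPM). Among 16 apoptosis regulators 0 were higher and 3 lower, namely Bak1 (-1.30), Cflar (-1.17) and Casp8 (-1.04), with a list median of -0.19 above 27.3% of random lists. The call of Casp8 ended when centred on the median gene (-0.97) and over cells called G1 (-0.93). The BH3-only gene Bcl2l11 had a log2 ratio of 0.98.

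Among lists with at least 8 members past the floor, neuronal and neuroendocrine genes had the highest median. All 13 members past the floor were at least 2-fold higher with panobinostat, with a median log2 ratio of 4.40, above all random lists. Some of them, such as Stmn3 (0.044 CPM with vehicle), Elavl3 (0.055) and Map2 (3.65), passed the floor only through panobinostat, which favours a higher ratio. With no floor, 20 of 21 members were at least 2-fold higher and 0 lower (median 4.27), against 4179 higher and 1870 lower of all 19394 genes. The largest shifts were in Stmn3 (4 and 1959 UMIs, log2 ratio 8.74, interval 7.38 to 10.6), the RNA-binding Elavl3 (7.53), chromogranin A, Chga (7.40), and the synaptic vesicle protein Syn1 (6.74). By level the most abundant was Stmn2, a regulator of microtubules in growing axons, which was 21.04-fold higher (26.3 to 553.5 CPM). Stmn2 had at least 1 UMI in 8.70% of thinned vehicle cells and 99.01% of thinned panobinostat cells, against 10.9% and 99.5% unthinned. The microtubule protein Map2 had a log2 ratio of 4.27. The secretory granule proteins Pcsk1n (6.76) and Scg5 (6.45) stood among the genes with the largest ratios.

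Meg3, a long noncoding RNA of the imprinted Dlk1-Dio3 region on chromosome 12 (109541001 to 109571726 in GRCm38), had the largest ratio of all genes under the naming rule. It had 29 UMIs with vehicle and 14880 with panobinostat, 446.9-fold higher (log2 ratio 8.80, interval 8.28 to 9.38). Unthinned, the vehicle UMIs lay in 7 of 2854 cells and those with panobinostat in 1575 of 2281. The interval treats UMIs as independent and leaves out this clumping. The casein Csn3 (6.14), the metallothionein Mt3 (6.09), Ly6c1 (5.45), Bex2 (4.84), Tceal5 (4.73), the glutathione S-transferases Gstt1 (4.48) and Gsta4 (4.43) and the cornified envelope gene Lce1f (4.32) followed. Ly6c1 and Lce1f have near-identical neighbours, so reads could be split between copies and their values are uncertain.

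**Figure D2:**
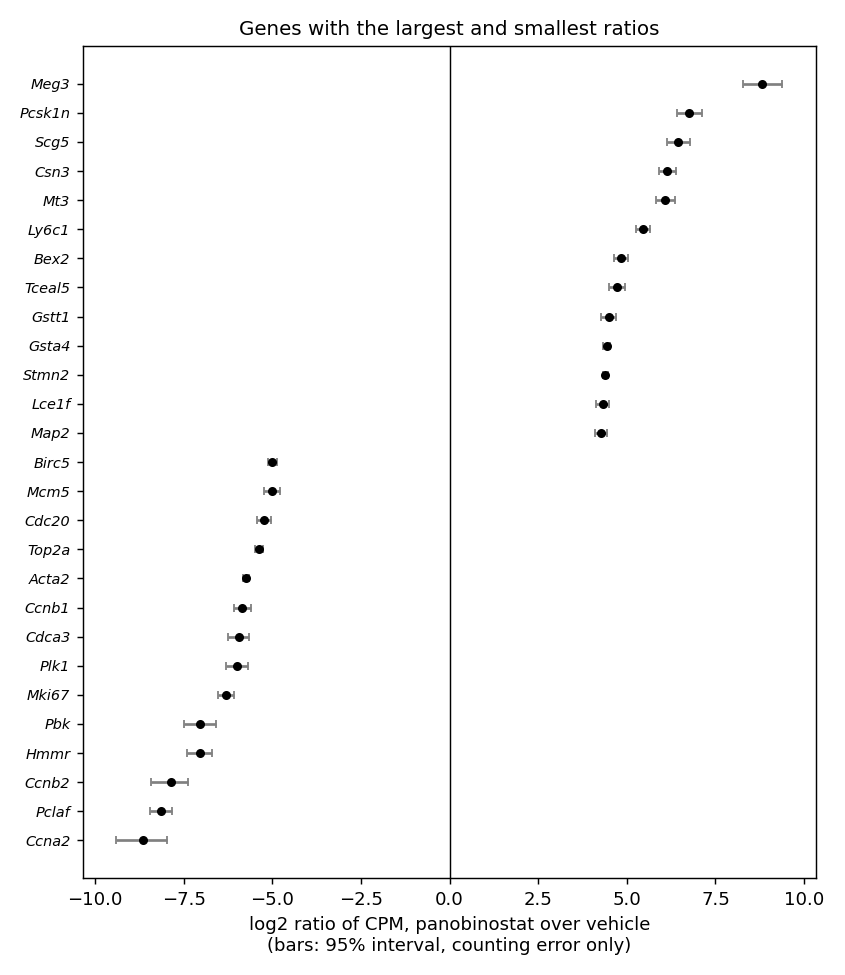
Log2 ratio of CPM, panobinostat over vehicle, for 13 of the 14 genes with the largest ratio and the 14 with the smallest, with 95% intervals for counting error. Ratios run from -8.64 for Ccna2 to 8.80 for Meg3, and no interval reaches 0.

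Genes of the contractile cytoskeleton were lower with panobinostat. Acta2, which encodes smooth muscle actin and lies on chromosome 19 (34241090 to 34255590 in GRCm38), was 53.3-fold lower (638.5 to 12.0 CPM, log2 ratio -5.74). Tagln, which encodes the actin-binding transgelin, was 13.3-fold lower (792.0 to 59.5 CPM). Of 18 actin cytoskeleton genes, 10 were at least 2-fold lower and 1, Synpo, was higher, with a median of -1.16 below all random lists. The light chain Myl9 (-3.12), filamin Flna (-1.69) and the tropomyosins Tpm4 (-1.56) and Tpm2 (-1.54) led this group. In the list of extracellular matrix and mesenchymal transition, 5 of 21 members were higher and 4 lower (median 0.14, above 87.5% of random lists). There the matrix protein Tnc was lower (-2.78) beside Acta2 and Tagln, and the metalloproteinase inhibitor Timp3 was higher (85.4 to 519.0 CPM, 2.60).

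Of 10 genes often raised by histone deacetylase inhibitors, 7 were at least 2-fold higher and 0 lower, with a median of 1.37 above all random lists. They included the tubulin Tubb3 (3.76), Clu, which encodes the chaperone clusterin (2214 to 6545 CPM, 1.56), and the metallothioneins Mt1 (1.70) and Mt2 (1.68). Of 8 genes of histone deacetylases themselves, Hdac11 (2.02) and Hdac5 (1.84) were higher and Hdac7 (-1.18) was lower, while Hdac6 (0.40) and the others stayed under 2-fold (median 0.07, above 64.4% of random lists). Among 9 acetyltransferases and bromodomain readers 2 were lower, Kat2a (-1.47) and Kat2b (-1.03), with a median of -0.63 above 1.88% of random lists. Crebbp (-0.88) and Brd2 (-0.74) stayed under 2-fold. Among 11 histone genes the linker histone H1f0 was higher (57.3 to 154.6 CPM, 1.43) and H2afx (-1.94) and H2afz (1243 to 441.1 CPM) were lower (median 0.27, above 92.3% of random lists). Over cells called G1 the calls of H2afx (log2 ratio -0.54) and H2afz (-0.31) ended. Those of Clu (0.99), Hdac7 (-0.92) and Kat2b (-0.83) ended there too. Histone transcripts that lack a poly(A) tail are counted incompletely in 3′ libraries, and which of these 11 genes this touches was not tested.

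Immediate early, oxidative stress, retinoic acid, interferon and NF-kB genes were more often higher than lower. Of 13 immediate early genes, 9 were higher and 0 lower (median 1.49, above all random lists), led by the transcription factors Klf2 (3.61), Fos (32.2 to 316.2 CPM, 3.30), Atf3 (2.63) and Egr1 (2.60). Of 14 metallothionein and oxidative stress genes, 7 were higher and 0 lower (median 1.08, above all random lists), among them Hmox1, the haem oxygenase (145.7 to 456.6 CPM, 1.65). Of 8 retinoic acid genes, 4 were higher, among them the binding proteins Crabp1 (4.46) and Crabp2 (3.39) and the enzyme Aldh1a1 (4.02), and 1, Aldh1a2, was lower (median 1.74, above all random lists). That median has an interval of -1.55 to 4.46 and was 0.44 with a floor of 1 CPM and 0.61 with none. In the interferon list 4 of 8 were higher and 2 lower (median 0.72, above 99.2% of random lists), with Rsad2 (3.91), Isg15 (3.05) and Cxcl10 (2.42) higher and Ifit2 (-1.51) lower. Its median ran from 0.15 in thinned cells to 1.90 with a floor of 50 CPM. In the NF-kB list 4 of 12 were higher and 1 lower (median 0.21, above 89.8% of random lists), with Nfkbiz (1.97), Csf1 (1.76) and Ccl20 (1.71) higher and Lif (-1.80) lower.

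Genes of ribosome biogenesis were lower. Of 14 members past the floor, 7 were at least 2-fold lower and 0 higher (median -1.08, below all random lists), led by the nucleolar proteins Gnl3 (-1.94), Nop56 (-1.92), Ncl (1077 to 309.7 CPM, -1.80) and Nolc1 (-1.58). Over cells called G1 the shift of the list median was smaller and the call of Nolc1 ended (-0.81). The 92 genes matched by a ribosomal protein name had a median of -0.25, above 1.16% of random lists. Of them Rps6ka2 (1.44), a kinase caught by its name, was higher, and the kinase Rps6ka4 (-1.04) and Rpl22l1 (-1.01) were lower. In glycolysis 1 of 15 was higher, the monocarboxylate carrier Slc16a3 (3.62), and 2 were lower, Pfkl (-1.71) and Ldha (631.7 to 248.8 CPM, -1.34), with a median of -0.32 above 12.2% of random lists. In the nuclear-encoded respiratory chain Ndufa1 (1.64) was the 1 of 16 that was higher (median 0.27, above 95.8% of random lists). The 13 mitochondrially encoded genes all stayed under 2-fold, with a median of 0.36 above 97.1% of random lists and mt-Co1 at 0.97.

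**Figure D3:**
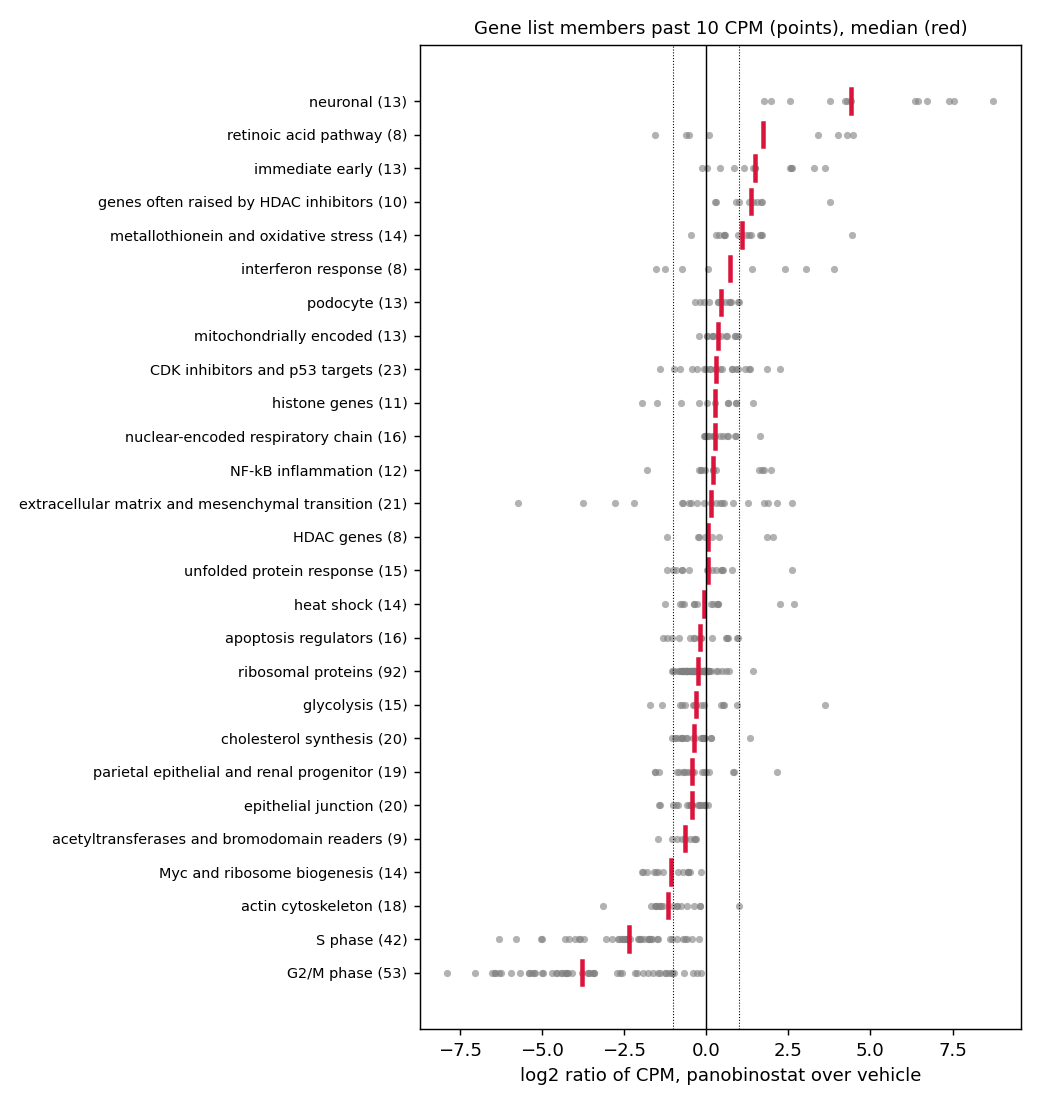
Log2 ratio of CPM, panobinostat over vehicle, of the members past 10 CPM in each gene list with at least 8 such members (grey points, number in brackets), with the list median in red and 2-fold bounds dotted. List medians run from -3.78 for G2/M genes to 4.40 for neuronal genes.

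The other lists had few members past 2-fold. Of 20 epithelial junction genes 2 were lower, Krt8 and the transcription factor Grhl2 (-1.39), with a median of -0.44 above 1.23% of random lists. Of 20 cholesterol synthesis genes 1 was higher, Dhcr7 (1.32), and 1 lower (median -0.36, above 5.57% of random lists). Among 14 heat shock genes Hspb8 (2.69) and Hspa1a (2.26) were higher and Hspd1 (-1.25) lower (median -0.07, above 54.6% of random lists), and Hspa1a has a near-identical copy that makes its value uncertain. Among 15 genes of the unfolded protein response Atf3 was higher, and Trib3 (-1.20) and Herpud1 (24.0 to 12.0 CPM) were lower (median 0.07, above 75.6% of random lists). Herpud1 lay at the bound (-1.0006), and its call ended without the called doublets (-0.997) and when centred on the median gene (-0.93). Of 6 Notch genes Jag2 (2.11) and Hes1 (103.4 to 292.0 CPM) were higher (median 0.26, above 77.9% of random lists). Of 4 Wnt genes Wnt4 (1.41) was higher and Ccnd1 lower (median -0.09, above 47.5% of random lists). The X-linked Xist, the 1 member analysed of the sex-linked list, stood at 310.0 and 361.1 CPM.

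Markers of other cell types were few. Of the proximal tubule list 2 members passed the floor and both were higher, the endocytic receptor Lrp2 (0.650 to 11.7 CPM) and Ggt1 (6.75 to 25.7 CPM). Of loop and distal tubule genes Ppp1r1a (2.62) and Cldn16 (2.55) were higher and Cldn19 (-1.21) lower. Of collecting duct genes Hsd11b2 (-2.11) was lower and Gata3 (0.61) stayed under 2-fold. Of endothelial genes Egfl7 (2.54) and Flt1 (2.74 to 15.5 CPM) were higher, while Pecam1 stood at 0.749 and 0.442 CPM. Of mesenchymal genes Thy1 (4.14) was higher, and Acta2 and Tagln were lower. Of immune genes Cd74 (41 and 3031 UMIs, log2 ratio 6.01) and Cd68 (4.11 to 65.5 CPM) were higher, while the pan-leukocyte gene Ptprc stood at 0.606 and 1.98 CPM. Lrp2, Ggt1, Ppp1r1a, Cldn16, Flt1, Thy1, Cd74 and Cd68 stood below the floor with vehicle and passed it only through panobinostat. Their higher ratios thus follow in part from the floor, and no shift of a cell type is read from them.

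All cells clustered together fell into 10 clusters, and 96.7% of cells (96.1 to 97.1) lay in clusters with at least 95% of cells from 1 library. With 1 library per treatment, such clusters may be libraries and not types, so their sizes are not compared between treatments. The leading genes of clusters 2 and 5, both of vehicle cells, were Top2a, Mki67 and other mitotic genes. Clusters 4, 6 and 8 were marked by Kitl, Clu and Gata3, by Folr1, Tagln, Acta2, Col4a1 and Sparc, and by Vim, Col4a1 and Sparc. Cluster 9 held 93 vehicle and 6 panobinostat cells of low depth (median 14673 UMIs) led by Acta1, Myl9 and Acta2. Its nuclear RNAs were low, with Xist at 8.01, Neat1 at 16.0 and Malat1 at 1157 CPM against at least 247.3, 263.0 and 4586 CPM in the other clusters, and its median share of mitochondrial counts was 2.16%. Cluster 10 held 9 vehicle and 63 panobinostat cells led by Pltp, Gal and Dcxr. No gene of the podocyte or progenitor lists was among the 10 leading genes of a cluster, although Pdpn, which encodes podoplanin and lies outside these lists, was 2nd in cluster 8 (5.45-fold over other cells). Of other lists, mesenchymal genes were among the leading 10 of clusters 3, 6 and 9, the loop gene Cldn16 in cluster 1 and the collecting duct gene Gata3 in cluster 4. No cluster was given a cell type name.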

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

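The settings without cluster 9 and with totals that leave out Malat1 and mitochondrially encoded genes were chosen after the data were seen, and the rest were planned. No paired analysis was possible because each treatment has 1 library and no test was run. Filters of 500 genes with 20% or 1000 genes with 10% mitochondrial counts removed 0 cells and so tested nothing. Removing the 5 called doublets left 873 genes higher and 973 lower.

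The counts followed thresholds by construction. At 1.5-fold 1708 genes were higher and 2059 lower, and at 4-fold 317 and 250. With a floor of 50 CPM 295 were higher and 369 lower. With 1 CPM 2344 were higher, against 1448 lower, and with no floor 4179 and 1870, and the cause of this turn in the balance was not tested. Over cells called G1 613 genes were lower and 779 higher. TMM factors gave 740 higher and 1232 lower, or 37.5% higher, and totals without Malat1 and mitochondrial genes 1054 and 881. No gene turned from higher to lower or back under any setting except 4 genes over G1 cells. Other folds and floors keep all ratios, and factors, centring and other totals shift them alike by a small amount. A call could not turn under these, so only the settings that changed cells or averaged over them tested this.

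Of 336 medians of the 28 lists with at least 6 members past the floor, under the 12 settings that changed cells or values, 331 stayed within their interval, which is wide for lists of few members. The S-phase median turned to 0.17 over G1 cells, where the G2/M median was -0.38, and G1 cells are picked by these lists. Both cover only members that still reached 10 CPM in those cells. The ribosomal protein median was -0.36 with TMM factors, -0.37 with DESeq2 factors and -0.17 with totals without Malat1 and mitochondrial genes, which shift all genes alike. For shorter lists the interval is only the range of members. The endothelial median of 2.52 was 2.41 with TMM, 2.40 with DESeq2, 2.59 when centred, 1.23 with a floor of 1 CPM, 0.37 with none, 2.63 over G1 cells, 2.49 as a mean over cells, 2.65 thinned and 2.60 with the totals above. Xist, alone in the sex-linked list, had 0.22, and 0.10 with TMM, 0.094 with DESeq2, 0.29 when centred, 0.219 without doublets, 0.35 over G1 cells, 0.23 as a mean over cells, 0.224 thinned, 0.20 without cluster 9 and 0.30 with those totals. With no floor the proximal tubule median went from 3.05 to 0.96 and the immune one to 0.72. The collecting duct median went from -0.75 to 0.64 as a mean over cells, and that of loop and distal tubule from 2.55 to 2.63 with those totals. Beyond these constructions the cause was not tested. Some medians took the opposite sign. The mesenchymal median went from -3.73 to 2.95 with a floor of 1 CPM and 2.24 with none, that of collecting duct to 0.48 and 0.61, and that of Wnt genes from -0.09 to 0.30 and 0.70. Over G1 cells the unfolded protein response went from 0.07 to -0.38. Medians of heat shock, histone deacetylase and matrix genes, near 0, took either sign. Centring ended the call of 6 named genes close to the bound, among them Casp8 and Kat2b. G1 cells alone ended that of 30, among them cell-cycle genes but also H2afx, H2afz, Clu, Hmox1 (0.94), Trp53inp1 (0.72), Casp8, Hdac7, Kat2b, Hspd1, Nolc1, Rps6ka4 and Rpl22l1. Some cell-cycle genes fell under the floor of 10 CPM with ratios still past 2-fold, such as Ccna2 (-3.12) and Hmmr (-2.85). Others, such as Top2a (-0.76), came under 2-fold. Over G1 cells the ribosome biogenesis median was -0.58. Without cluster 9 the call of Synpo ended at 0.991.

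Differences in shares of cells, panobinostat minus vehicle in percentage points, depended on thinning because the libraries differ in depth. Unthinned, the difference for Pax8 turned from -5.18 to 2.97. For Pax2 it went from -13.4 to -2.31, for Synpo from 9.88 to 22.6, for Podxl from 5.28 to 15.4 and for Wt1 from 1.26 to 2.32. Thinned to the 25th percentile, it was 7.43 for Podxl and -67.0 for cells called S or G2/M, against -65.03. At Leiden resolution 0.3, 98.7% of cells lay in clusters at least 95% from 1 library.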

Other observations

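Gene families outside the planned lists also differed between the libraries. All lists of this paragraph and the next were chosen after the data were seen. Of 17 glutathione S-transferase genes past the floor, 12 were at least 2-fold higher with panobinostat and 0 lower, with a median log2 ratio of 1.36, led by Gstm6 (39 and 3106 UMIs, 6.12), Gstm7 (4.98) and Gstk1 (3.71). Members of the Gstm cluster are near-identical, so their single values are uncertain. Of 11 genes of antigen presentation by MHC class I and II, 8 were higher and 0 lower (median 1.73). The class II genes H2-Ab1 (1.51 to 46.6 CPM, 4.95), H2-DMa (4.35) and H2-Eb1 (3.66) stood beside Cd74 (6.01), which the immune list also holds, and the class I light chain B2m went from 151.5 to 349.9 CPM (1.21). Of 28 lysosomal genes 9 were higher and 0 lower (median 0.83), among them the cathepsins Ctsf (2.86) and Ctsl (880.4 to 3463 CPM, 1.98) and progranulin, Grn (1.71).

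Of 8 genes of the X-linked Bex and Tceal families, 5 were higher and 0 lower (median 2.09). Of 12 cornified envelope genes, which serve the skin barrier, 7 were higher and 1 was lower (median 1.42), with Crct1 (13.5 to 171.9 CPM, 3.67), Sbsn (3.17) and Lor (2.71) higher and Ivl (-1.16) lower. Of 21 imprinted genes past the floor 5 were higher, Meg3, Mest (2.09), Plagl1 (1.88), Nnat (1.39) and Snrpn (1.25). Phlda2 (-1.82) and Ppp1r9a (-1.67), 2 genes, were lower, and the median of 0.11 is not far from 0. Below the floor, Dlk1 had 5 UMIs with vehicle and 705 with panobinostat (6.94), and Dio3 had 19 and 9 (-1.28). Of 19 germline genes 1, Tex15, passed the floor (3.22 to 25.7 CPM). The nuclear RNA Malat1 took 0.734% of all UMIs with vehicle and 4.18% with panobinostat, and Neat1 went from 466.4 to 1120 CPM. Of 10 genes of Rest and its corepressors, 0 were higher and 0 lower (median -0.13).

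The tests below that were chosen only after the result was seen are the match of clusters between libraries and the test of the cell-cycle lists. The gain of neuronal transcripts was weighed against a few cells of another type, a shift in called phases and a lower level of Rest, the repressor of neuronal genes. In thinned panobinostat cells 98.96% held UMIs of at least 3 of the 13 genes, against 5.25% of vehicle cells, which argues against a few cells of another type as their only holders, while their spread through free RNA was not tested and stays open. Over cells called G1 the median log2 ratio was 5.37, which argues against the mix of called phases as the whole cause. Phase calls are relative, so cells called G1 may differ in cycling between the libraries, and a link to leaving the cycle was not tested. Rest stood at 82.5 and 64.5 CPM (log2 ratio -0.36, interval -0.40 to -0.31), which argues against its transcript level as the whole cause. With 1 library per treatment, a difference between the 2 libraries other than the drug cannot be told apart from the drug, and an effect on Rest protein or on deacetylase activity at its targets may be open and was not tested.

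Clusters of the 2 libraries resembled each other in pairs. For each cluster of at least 100 cells the contrast with the rest of its own library was taken over 8777 genes outside the cell-cycle lists. Panobinostat cluster 1 correlated best with vehicle cluster 2 (r = 0.44), cluster 4 with cluster 7 (0.58) and cluster 8 with cluster 6 (0.69), across genes, which are not independent replicates. The lowest of these, 0.44, is consistent with the hypothesis that 3 subpopulations were present in both libraries, found and tested on the same data. Vehicle clusters were then pooled by their best match, 2 and 3 for cluster 1 (cluster 3 at r = 0.29), 5 and 7 for cluster 4 (cluster 5 at r = 0.57) and 6 for cluster 8, so that the mitotic clusters 2 and 5 were merged with others. Between cells matched in this way 601 genes were at least 2-fold higher with panobinostat in all 3 pairs and 753 were lower in all 3. The retinoic acid median was 2.98, -0.01 and 3.20 in the pairs of clusters 1, 4 and 8. Its sign-test intervals over members were -1.34 to 5.13, -2.76 to 4.87 and -1.41 to 4.11. All include 0 and overlap, so no difference between the pairs is read from them. The 1 gene that was higher in 1 pair and lower in another was Slc29a1, a nucleoside transporter, with a log2 ratio of 1.32 in the pair of cluster 1 and -1.22 in that of cluster 8.

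The lower cell-cycle lists could come from a change in the mix of these subpopulations. The median log2 ratio of the G2/M list was -3.64 or lower in all 3 pools. In cluster 8 against vehicle cluster 6, its only match, it was -4.09 (interval -5.12 to -3.41), which argues against the loss of other clusters as the cause there. In clusters 1 and 4 it was -4.55 and -4.78 against the mitotic clusters 2 and 5. Against clusters 3 and 7 it was -0.81 (-1.22 to -0.53) and -1.02 (-1.60 to -0.65). The latter medians rest on 34 and 33 members past the floor, against 54 for clusters 2 and 5, so the gene sets differ. A loss of clusters 2 and 5 thus cannot be told apart from lower cell-cycle genes within these 2 subpopulations, and the match of cluster 3 is weak. Any other difference between the libraries stays open as well.

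In cluster 10, 9 vehicle cells lay with 63 panobinostat cells. Panobinostat-treated cells in the vehicle library were tested by the summed CPM of the 14 genes with the largest ratios. These 14 genes were picked from the same 2 libraries, of which the 9 cells are a small part. The median sum was 51.8 in these 9 cells, below the 5th percentile of panobinostat cells (948.5) and near the 23.4 of other vehicle cells. The highest of the 9 cells, at 140.1 CPM, also lay below the lowest panobinostat cell of cluster 10 (441.1). These values argue against treated cells. For the 14 genes with the smallest ratios the median sum of the 9 cells was 302.9 CPM, against 1674 in other vehicle cells. No biological explanation was tested.

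Outside cluster 10, 11 vehicle cells reached the 5th percentile of panobinostat cells in that sum, with the highest at 2544 CPM. The 6 panobinostat cells of cluster 9 had a median of 0.166% mitochondrial counts, against 6.96% in all panobinostat cells.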
